A study of Drosophila melanogaster with 21 samples.

How the data were processed

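Gene expression was measured on 21 spotted two-colour Drosophila arrays from the Canadian Drosophila Microarray Centre, 3 in each of 7 groups. On each array, labelled total RNA from treated cells or salivary glands was hybridised together with RNA from ethanol-treated controls, so that each spot gives a treated and a control signal. The deposited raw files hold spot foreground and background intensity for both dyes, and the deposited series matrix holds 1 log2 ratio of treated over control per spot, per the file headers. The scale of the matrix values is log2, since they match the log2 of the raw signal ratio within 1e-04 for 33.7 to 81% of the spots of an array. Their direction is treated over control on each of the 21 arrays. How the authors normalised and centred them is not given in the sources used here. The column medians of the matrix ran from −0.746 to 0.669, and the matrix values correlated with the raw log2 ratios across spots with r of 0.872 to 0.985. With the normalised log2 ratios used as main values here, r was lower, at 0.432 to 0.885.

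The main values were computed from the raw intensities with R 4.3.3 and limma 3.58.1. Background was subtracted with the normexp method (offset 50), and each array was normalised by a loess curve of log2 ratio on mean log2 intensity, in which control spots and spots set aside in the raw files had no weight. Each array has 27648 spots in 48 subarrays of 24 rows and 24 columns, in 2 layouts. The 4118 control spots and 28 spots whose gene differs between the layouts were left out. The remaining spots were averaged per clone name, giving 10474 probes. Of these, 9350 carried a gene number, with 9348 different numbers, of which 8712 matched a locus tag of the reference gene table and 465 matched exactly 1 synonym, while 171 matched neither and kept their number as the name. The 1124 probes without a gene name were tested and counted but not joined to a gene. The gene table (Release 6 of the fly genome) was used for names alone, and no positions are given.

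The dye of the treated RNA was taken from the raw file headers. On 4 arrays the treated RNA was in Cy3 (replicate 3 of the glands, of cycloheximide, and of 20E with cycloheximide, and replicate 2 of the 2 h group), and on the other 17 it was in Cy5. For 2 h replicate 2 the sample label states Cy5, whereas the header and the direction of the matrix values give Cy3. The header was used for all values unless the orientation of the label is named. For the other groups of Kc167 cells the label's orientation leaves the log2 values as they are. It changes their p values through the spread that the jointly fitted arrays share.

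The depth behind each value is the signal over background. The median foreground per array was 159 to 969 in the treated channel, over a background of 5.42 to 81.5, and 141 to 768 in the control channel, over a background of 1.96 to 55.1. The share of probes above the 95th percentile of the 768 empty spots was 53.3 to 93.3% per array, and 0.0638 to 1.05% of gene spots lay at or below their local background. The highest signal was 11467 to 59213, and 20 to 1209 spots per array were set aside in the files. The number of arrays, 3 per group, limits the precision.

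Every test was a limma test per probe (lmFit and eBayes) with Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. A probe needed values on at least 2 of the 3 arrays of each group. The 6 groups of Kc167 cells were fitted together (18 arrays, 10460 probes), the glands alone (10474 probes), and the difference between glands and cells on the 6 arrays of both groups (10466 probes). Each group was tested against its own ethanol controls, and 6 differences between groups were tested as contrasts. The fits had no dye term and no block. Error terms printed as SD are across the 3 arrays of a group, and intervals of differences are 95% intervals from limma. Nothing in the sources says that the replicates are separate cultures, so the p values may measure technical spread.

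A set of 27 gene lists was tested with camera at a preset correlation of 0.01 between genes, with 1 probe per gene (the brightest) and Benjamini-Hochberg adjustment over the lists of a comparison. Each list was also tested with an estimated correlation, and with fry, whose p asks whether a list's genes move on balance one way, without comparing them with other genes. Of the lists, 20 cover ecdysone targets, ecdysteroid metabolism, heat shock proteins, glue and late puff genes, cell death, autophagy, cell cycle, ribosomal proteins, ribosome biogenesis, proteasome, glycolysis, labile regulators, antimicrobial peptides, cytoskeleton, adhesion, chitinases and histones, and 7 are markers of blood cells, salivary gland, fat body, muscle, neurons and glia, gut, and imaginal disc. Lists, tests, groups and the first set of alternatives were chosen before the data were examined. So was the rule for named genes in each comparison with control. It takes the 12 largest called rises and 8 largest called falls with all 3 arrays on one side. To these it adds all measured early ecdysone regulators, except with cycloheximide alone, where up to 4 called ones are taken. Of each other list it takes up to 4 called members, or the brightest ones where none is called.

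The arrays were checked for pairing, hybridisation day and shared controls. Replicates with the same number correlated, after removal of the group means, between 20E with cycloheximide and cycloheximide alone (r across probes of 0.28, 0.5 and 0.65), and were therefore also fitted as pairs. Between cycloheximide alone and 20E 0.5 µM for 4 h these correlations were 0.01, 0.58 and 0.23, and between the other groups compared they were not all positive. The arrays fall into 7 hybridisation days, taken from dates in the image names of the raw file headers. Arrays without a date would be placed last, as a day of their own. The 3 PonA arrays hold the last place, so a missing date is not excluded for them. The 3 PonA arrays make up one of them and the 3 gland arrays another, so that day and group cannot be told apart for these. Some control extracts served several arrays. Per the labels, both cycloheximide groups shared their control extract at each replicate number, and 2 of these 3 extracts also served 20E 0.5 µM for 4 h (its replicates 2 and 3). The PonA and 2 h labels describe their RNA extracts in identical words, and the label of gland replicate 3 gives its treated and control extracts the same RNA concentration and absorbance ratio. The 3 Kc167 arrays with the treated RNA in Cy3 are all the arrays of 1 day, so that a dye term in the Kc167 fit holds dye and day together. Correlations between groups are given with values simulated under shared controls. Expected numbers of shared probes assume independent lists and are given only for groups without a shared control extract. Neither allows for a dye orientation that groups have in common, and the expected numbers do not allow for their joint estimate of the spread.

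The alternatives tried were no background subtraction, loess within each print-tip block, the series matrix values, a filter on probes not above local background, a minimum change of 1.5-fold, a dye term, a fit of the compared arrays alone, the control extract as a random block, the replicate number as a block, and each array left out in turn. After the data were seen, the label orientation of 2 h replicate 2, a fit without that array, the hybridisation day as a block, a filter on probes at the level of empty spots, and matrix values with column medians subtracted were added. The consensus correlation within blocks was 0.201 for the day and 0.244 for the control extract. The matrix moved the median of all probes to −0.5 with PonA, 0.16 with cycloheximide, −0.15 at 2 h, −0.13 with 10 µM 20E and −0.11 in glands, and changes of gene groups under the matrix are therefore read relative to that median.

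The procedure was tested on simulated data. With known changes planted at the size of the 4 h 20E group, 52.2% of changes of 1.5-fold, 82.1% of changes of 2-fold and 100% of changes of 4-fold were called, with 8 false calls among 164. For the glands alone these shares were 41.8, 79.1 and 92.4%. For a difference between 2 groups of cells they were 38.8, 71.6 and 93.9%, for the interaction 22.7, 55.2 and 89.4%, and for a difference between glands and cells 19.4, 53.7 and 89.4%. In the order of these 4, false calls were 6 among 148, 7 among 143, 12 among 123 and 9 among 117. Data without planted changes, tested for the 4 h 20E group alone, gave 0 calls. The simulated noise was independent between probes and between arrays. It held no dye effect, no day effect and no shared control extract, so the shares and false calls do not cover such effects. The result of 1 gene called with PonA is not reported here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.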

Results

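Transcript levels were measured in Drosophila cells and tissue exposed to ecdysteroids, the steroid hormones that drive moulting and metamorphosis. Kc167, a cell line derived from embryos, was treated with 20-hydroxyecdysone (20E, the active hormone of the fly) at 0.5 µM for 2 h, 0.5 µM for 4 h or 10 µM for 4 h. A further group received ponasterone A (PonA, 25-deoxy-20-hydroxyecdysone, a plant ecdysteroid) at 0.0625 µM for 4 h. Other Kc167 cultures received cycloheximide (CHX, an inhibitor of translation) at 100 µM for 4 h, alone or together with 0.5 µM 20E. Salivary glands of late 3rd instar larvae of the Oregon R strain were treated with 0.5 µM 20E for 4 h. Each of the 7 groups had 3 two-colour arrays (21 in all), each with ethanol-treated control RNA in the other dye. Values are log2 of treated over control, as mean ± SD over 3 arrays. The median treated signal per array was 159 to 969 over a background of 5.42 to 81.5. Between 53.3 and 93.3% of probes lay above the level of empty spots, with 53.3, 63.4 and 53.3% on the gland arrays. Across probes, the arrays of a group correlated with r of 0.34 to 0.67 for PonA, 0.31 to 0.39 for 20E with CHX, 0.15 to 0.25 for 20E 0.5 µM at 4 h and 0.08 to 0.24 for 20E 10 µM. The range was 0.07 to 0.33 for glands, −0.22 to 0.32 for CHX and −0.24 to 0.41 for 20E at 2 h. Probes are not independent replicates.

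**Figure D1:**
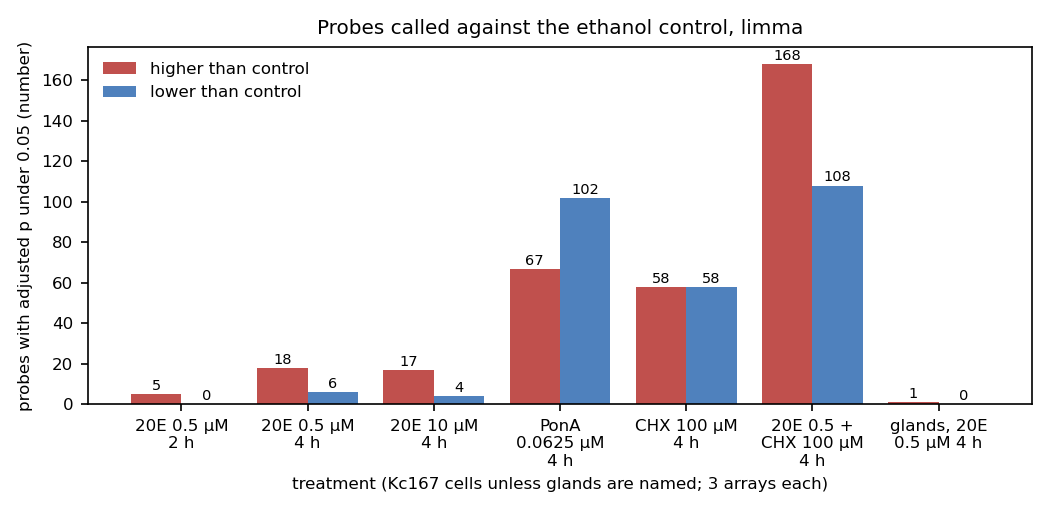
Number of probes with a limma adjusted p under 0.05 against the ethanol control in each group of 3 arrays, higher (red) and lower (blue) than control. The counts run from 1 probe in glands to 276 probes in Kc167 cells treated with 20E and CHX.

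The 2 h treatment asked which transcripts respond early to 20E. At 2 h, 3 named genes rose in Kc167 cells. Rrp46 (CG4043), which encodes a subunit of the RNA exosome, rose by 1.51 ± 0.37 (SD, n = 3, adjusted p = 0.0382). CG5346 rose by 1.46 ± 0.55 (SD, n = 3, adjusted p = 0.0382). Eip75B (CG8127), an early ecdysone-induced nuclear receptor, rose by 0.71 ± 0.06 (SD, n = 3, adjusted p = 0.0382). All 3 were higher than control on 3 of 3 arrays. The classic targets MsrA (CG7266, known as Eip71CD, a methionine sulfoxide reductase) and Cth (CG5345, known as Eip55E, cystathionine gamma-lyase) stood at 1.41 ± 0.47 (SD, n = 3) and 0.83 ± 0.47 (SD, n = 3), without passing the test over all probes. The ecdysone receptor gene EcR stood at 0.52 ± 0.13 (SD, n = 3) and did not pass either.

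Among the 19 measured early and early-late ecdysone regulators, 1 rose at 2 h (1 also when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.328). The 17 other known ecdysone-inducible genes shifted up as a list (mean 0.23, or 0.09 relative to the median of the series matrix, median 0.05, adjusted p = 0.0389). The call was lost with a correlation estimated from the data (adjusted p = 0.136 with an estimated correlation). None of them was called over all probes, and 2, MsrA and Cth, passed when adjusted over the list alone. In all, 5 probes were called at 2 h, all of them higher than control. They include 2 clones without a gene name (1.98 and 1.64 on the log2 scale, chosen after their values were seen). At 2 h, 459 probes had an unadjusted p under 0.05 against 523 expected. The calls at 2 h depend on the dye orientation of replicate 2, for which label and file header differ. With the orientation of the label 0 probes were called. Eip75B was then 0.28 (adjusted p = 0.787), Rrp46 0.79 (adjusted p = 0.752) and CG5346 0.64 (adjusted p = 0.763). The call of CG5346 was also lost with a dye term (adjusted p = 0.063). Leaving out any 1 of the 3 arrays also left 0 calls, as did a fit of these 3 arrays alone.

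The 4 h treatment with 0.5 µM 20E asked which genes the hormone changes in these cells. The largest rise was that of MsrA, at 2.29 ± 0.72 (SD, n = 3, adjusted p = 0.00215). CG15482 rose by 1.62 ± 0.57 (SD, n = 3, adjusted p = 0.0039), and CG5346 by 1.61 ± 0.43 (SD, n = 3, adjusted p = 0.00592). Pss, phosphatidylserine synthase, rose by 1.29 ± 0.31 (SD, n = 3, adjusted p = 0.00916). Other rises were those of MFS10, a transporter of the major facilitator family (1.17 ± 0.24, adjusted p = 0.0039), and grsm, an aminopeptidase (1.11 ± 0.17, adjusted p = 0.00215). Further ones were those of PRL-1, a phosphatase (1.08 ± 0.40), and of Cth (1.02 ± 0.42, adjusted p = 0.014). Eip75B rose by 0.76 ± 0.27 (SD, n = 3, adjusted p = 0.0039). The falls were smaller and included CG10383 (−0.94 ± 0.24, adjusted p = 0.00352), Pfk, phosphofructokinase of glycolysis (−0.56 ± 0.08, adjusted p = 0.0132), and wgn, a tumour necrosis factor receptor (−0.54 ± 0.04, adjusted p = 0.0447).

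Of the 19 early regulators, Eip75B alone was called at 4 h (2 genes when adjusted over the list alone). vri, an early transcription factor gene, stood at 0.90 ± 0.86 (SD, n = 3, adjusted p = 0.305), and EcR at 0.17 and Eip74EF at 0.10 did not pass. The 75 ribosomal protein genes lay on average 0.30 above control (67 positive, none called, adjusted p = 2.53e-09 by camera). The shift was not called with an estimated correlation (adjusted p = 0.601 with an estimated correlation) or with a dye term (adjusted p = 0.732). Their mean was 0.71 on replicate 2 against 0.03 and 0.17 on the others, and 0.15 relative to the median of the series matrix. The 11 large heat shock and chaperone genes lay lower (mean −0.55, none called, adjusted p = 0.0136, and adjusted p = 0.601 with an estimated correlation, 0.14 with a dye term). Their array means were −0.41, −1.04 and −0.24. The 44 proteasome genes lay 0.10 higher (none called, adjusted p = 0.0466, and adjusted p = 0.601 with an estimated correlation), but turned to lower with a dye term (adjusted p = 0.473), were not called without background subtraction (adjusted p = 0.208) and lay lower, at −0.01, relative to the median of the series matrix. With the hybridisation day as a block, 1 of these 3 lists kept its call.

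In total 24 probes were called after 4 h of 0.5 µM 20E, 18 higher (15 named genes) and 6 lower (5 named genes), and 1097 had an unadjusted p under 0.05. With a dye term 4 of the 24 kept their call, among them MsrA (adjusted p = 0.0229), grsm (adjusted p = 0.0229) and MFS10 (adjusted p = 0.031). With hybridisation day as a block 20 kept their call, and wgn (adjusted p = 0.0652) lost it. Leaving out replicate 2 left 6 calls. A fit of the 3 arrays of this group alone called 0 probes, the series matrix 11, and the label's dye orientation of 2 h replicate 2 gave 4 (grsm, PRL-1, CG10383 and Pfk).

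**Figure D2:**
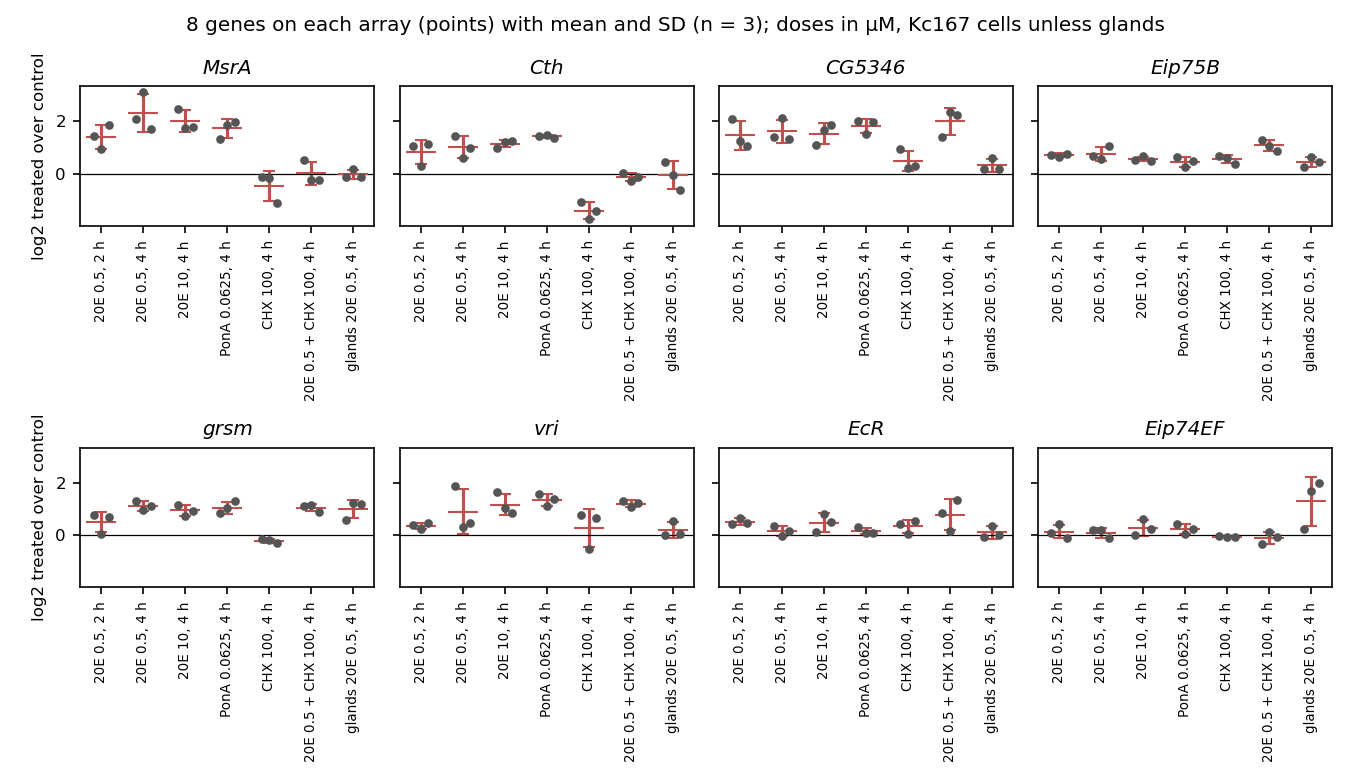
Log2 ratio of treated over control on each array (grey points) for 8 genes in the 7 groups of 3 arrays, with mean and SD in red. MsrA reached 2.29 with 0.5 µM 20E at 4 h and 0.02 with 20E and CHX, while Cth had its lowest mean, −1.39, with CHX alone.

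The treatment with 10 µM 20E for 4 h asked the same at a higher dose. The named genes with the largest rises were again MsrA (2.00 ± 0.41, SD, n = 3, adjusted p = 0.00717) and CG5346 (1.53 ± 0.40, adjusted p = 0.011), followed by Rrp46 (1.30 ± 0.27, adjusted p = 0.0417), Pss (1.25 ± 0.42, adjusted p = 0.0122) and Cth (1.15 ± 0.15, adjusted p = 0.01). Dronc, an initiator caspase of apoptosis, rose by 0.99 ± 0.30 (SD, n = 3, adjusted p = 0.00717), as the 1 called member of the 15 cell death genes. Idgf3, an imaginal disc growth factor, rose by 0.70 ± 0.29 (SD, n = 3, adjusted p = 0.0122), and Eip75B by 0.56 ± 0.09 (SD, n = 3, adjusted p = 0.0426). Lower genes included Vha100-2, a subunit of the vacuolar proton pump (−0.79 ± 0.32, adjusted p = 0.0417), and CG31305 (−0.68 ± 0.13, adjusted p = 0.016).

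Of the 19 early regulators, 1 was called at 10 µM (2 adjusted over the list alone), and vri at 1.17 ± 0.41 (SD, n = 3, adjusted p = 0.114) was not. The 17 other ecdysone-inducible genes lay higher as a list (mean 0.31, median 0.06, 2 called, 2 adjusted over the list alone, adjusted p = 0.0427, and adjusted p = 0.144 with an estimated correlation). In all, 21 probes were called, 17 higher and 4 lower, with 871 at an unadjusted p under 0.05. Of the rises, 11 were shared with 0.5 µM 20E at 4 h, against 0.0293 expected from independent lists. No call was left without replicate 2 or without replicate 3, and 45 without replicate 1. The label's dye orientation of 2 h replicate 2 also ended every call (0 probes), as did a fit of these 3 arrays alone, while the series matrix gave 79. That orientation leaves the values of this group unchanged (MsrA again 2.00, adjusted p = 0.122 by limma). It acts through the spread shared by the Kc167 arrays. With a dye term 5 of the 21 kept their call, MsrA (adjusted p = 0.0381) and Dronc (adjusted p = 0.0381) among them. With the day as a block 12 did, and Eip75B (adjusted p = 0.0686), Rrp46 (adjusted p = 0.102) and Vha100-2 (adjusted p = 0.107) did not.

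PonA at 0.0625 µM for 4 h showed which genes another ecdysteroid changes. CG5346 (1.83 ± 0.27, SD, n = 3, adjusted p = 0.00135), MsrA (1.72 ± 0.36, adjusted p = 0.00496), Pss (1.49 ± 0.42, adjusted p = 0.0015) and Cth (1.42 ± 0.06, adjusted p = 0.000954) rose. So did cact, the inhibitor of the Toll pathway's transcription factors (1.55 ± 0.43, adjusted p = 0.00163), and vri (1.36 ± 0.23, adjusted p = 0.0207). Further rises were those of Hsp27, a small heat shock protein (1.26 ± 0.28, adjusted p = 0.00498), and of eater, a phagocytic receptor of blood cells (1.22 ± 0.42, adjusted p = 0.0207). Eip75B rose by 0.46 ± 0.19 (SD, n = 3, adjusted p = 0.0397). In the series matrix it was −0.07 (adjusted p = 0.705), where the median of all probes was −0.5, and with the column medians subtracted 0.40 (adjusted p = 0.0489). Among the falls were those of Aldh, aldehyde dehydrogenase (−1.32 ± 0.43, adjusted p = 0.00284), and Xrp1, a stress-responsive transcription factor (−1.23 ± 0.76, adjusted p = 0.0159).

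Other genes that fell with PonA were Nopp140, a nucleolar protein (−0.86 ± 0.36, adjusted p = 0.00284), and RnrL, the large subunit of ribonucleotide reductase (−0.85 ± 0.48, adjusted p = 0.0362). LanB1, a laminin chain (−0.95 ± 0.09, adjusted p = 0.0353), and grim, an activator of apoptosis (−0.80 ± 0.32, adjusted p = 0.0267), fell as well. Of the 19 early regulators, 2 were called, Eip75B and vri (2 adjusted over the list alone), and of the 17 other ecdysone-inducible genes also 2 (3 adjusted over the list alone). The 5 small heat shock genes lay higher as a list (mean 0.41, Hsp27 called, 2 adjusted over the list alone, adjusted p = 0.034, and adjusted p = 0.332 with an estimated correlation). The 15 glycolysis genes lay lower (mean −0.18, 13 negative, none called, 4 adjusted over the list alone, adjusted p = 0.0286, and adjusted p = 0.177 with an estimated correlation), but by −0.01 relative to the median of the series matrix. The 75 ribosomal protein genes lay 0.18 higher (array means −0.03, 0.15 and 0.42, 59 positive, 1 called higher and 1 lower, adjusted p = 0.012, and adjusted p = 0.908 with an estimated correlation), but turned to lower with a dye term (adjusted p = 0.0476).

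PonA changed 169 probes, 67 higher (60 named genes) and 102 lower (83 named genes), with 1361 at an unadjusted p under 0.05. Leaving out replicate 3 left 15 calls and leaving out replicate 2 left 61. With a dye term 30 probes were called higher and 31 lower. Of the 169, 46 kept their call. Among the genes named here, vri (adjusted p = 0.0658), eater (adjusted p = 0.0737), grim (adjusted p = 0.0864), Xrp1 (adjusted p = 0.0942), RnrL (adjusted p = 0.173) and Eip75B (adjusted p = 0.194) lost it. The 3 PonA arrays had the same dye orientation and form a day of their own, for which a missing date is not excluded. Treatment and day therefore cannot be told apart. With the day as a random block 20 probes were called higher and 12 lower, and the same 6 genes and LanB1 (adjusted p = 0.173) lost their calls. The label's dye orientation of 2 h replicate 2 also ended that of Eip75B (adjusted p = 0.315). In a fit of the 3 PonA arrays alone 2 probes were called.

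CHX alone showed what the inhibition of translation does to the transcripts of these cells. E(spl)mbeta-HLH, a Notch target of the Enhancer of split complex, rose by 1.73 ± 0.29 (SD, n = 3, adjusted p = 0.000511). The emc gene, a negative regulator of bHLH proteins, rose by 0.68 ± 0.29 (SD, n = 3, adjusted p = 0.00586). CG13868 rose by 1.93 ± 0.42 (SD, n = 3, adjusted p = 0.00138) and the kinase gene Slik by 1.00 ± 0.08 (SD, n = 3, adjusted p = 0.000511). Eip75B rose by 0.56 ± 0.15 (SD, n = 3, adjusted p = 0.0165, but 0.251 with the label's dye orientation of 2 h replicate 2). The genes E(spl)mbeta-HLH and emc were the 2 called of 19 immediate early and labile regulators (2 adjusted over the list alone, camera adjusted p = 0.145). Cth fell by 1.39 on the log2 scale (SD 0.33, n = 3, adjusted p = 0.000634), opposite in sign to its rise with 20E or PonA. Other falls were those of Loxl1, a lysyl oxidase (−1.53 ± 0.55, adjusted p = 0.0133), Inos, inositol phosphate synthase (−1.45 ± 0.48, adjusted p = 0.00536), and eIF2alpha, a translation initiation factor (−1.11 ± 0.37, adjusted p = 0.000628).

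Glycolysis genes fell with CHX. Of the 15 measured, 11 were negative and 3 were called. These were Gapdh1 (−0.93 ± 0.21, adjusted p = 0.000629), Eno (−0.73 ± 0.50, adjusted p = 0.0332) and Ald1 (−0.66 ± 0.35, adjusted p = 0.0257), which encode a dehydrogenase, enolase and aldolase of the pathway. When adjusted over the list alone, 7 passed. The list mean was −0.31 (adjusted p = 1.08e-05), and of the 31 list calls in all comparisons this was the 1 that held with an estimated correlation (adjusted p = 0.00532). The 75 ribosomal protein genes lay lower (mean −0.22, 55 negative, adjusted p = 1e-06, and adjusted p = 0.368 with an estimated correlation). Of these genes 3 were called, among them RpL4 at −1.07 ± 0.36, and 6 passed when adjusted over the list alone. The list had array means of −0.22, 0.31 and −0.77, the last on the array with the dyes swapped. The 11 large heat shock and chaperone genes also lay lower (mean −0.69, 10 negative, none called, 4 adjusted over the list alone, adjusted p = 0.000115, and adjusted p = 0.287 with an estimated correlation). Their array means were −0.26, −1.55 and −0.27. Replicate 2 of CHX, of 20E with CHX and of 0.5 µM 20E at 4 h share a control extract and a day.

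A further 4 lists shifted down with CHX at the preset correlation, each with a larger p when the correlation was estimated. The 44 proteasome genes had a mean of −0.15 (array means −0.16, 0.10 and −0.39, none called, adjusted p = 0.00127, and adjusted p = 0.362 with an estimated correlation). The 17 other ecdysone-inducible genes had a mean of −0.25 (Cth called, 1 higher and 2 lower adjusted over the list alone, adjusted p = 0.0177, and adjusted p = 0.111 with an estimated correlation). The 23 actin and tubulin genes had a mean of −0.17 (none called, adjusted p = 0.0373, and adjusted p = 0.259 with an estimated correlation). For the 14 muscle markers it was −0.21, or −0.07 relative to the median of the series matrix (array means 0.01, −0.49 and −0.16, none called, 2 adjusted over the list alone, adjusted p = 0.032, and adjusted p = 0.259 with an estimated correlation). Without background subtraction the ecdysone-inducible list (adjusted p = 0.0815), the actin and tubulin list and the muscle markers (both adjusted p = 0.176) were not called. With a dye term the muscle markers were not called either (adjusted p = 0.0509). CHX changed 116 probes, 58 higher and 58 lower, with 1182 at an unadjusted p under 0.05. With a dye term 113 of the 116 kept their call, while 30 probes were called without replicate 1, 24 with the series matrix and 0 in a fit of the 3 CHX arrays alone.

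With 20E and CHX together, the comparison with ethanol showed hormone and inhibitor at once. Rrp46 rose by 2.69 ± 0.42 (SD, n = 3, adjusted p = 7.13e-05) and CG5346 by 1.99 ± 0.51 (SD, n = 3, adjusted p = 0.000307). MFS10 rose by 1.68 ± 0.53 (SD, n = 3, adjusted p = 8.93e-05) and Dronc by 1.21 ± 0.39 (SD, n = 3, adjusted p = 0.000297). Of the 19 early regulators, 17 were positive and 3 were called. They were Eip75B (1.08 ± 0.22, adjusted p = 9.24e-05), vri (1.20 ± 0.13, adjusted p = 0.0247) and EcR (0.78 ± 0.59, adjusted p = 0.0236, but 0.0731 with the label's dye orientation of 2 h replicate 2). When adjusted over the list alone, 4 were called. The list shifted up (mean 0.26, adjusted p = 0.00373, and adjusted p = 0.271 with an estimated correlation). MsrA at 0.02 ± 0.44 (SD, n = 3) and Cth at −0.12 ± 0.14 (SD, n = 3) were not called. The largest falls of named genes were those of Loxl1 (−2.37 ± 0.50, adjusted p = 0.000307) and Aldh (−1.69 ± 0.43, adjusted p = 0.000297). FASN1, fatty acid synthase (−1.12 ± 0.52, adjusted p = 0.00507), and ifc, a sphingolipid desaturase (−1.06 ± 0.12, adjusted p = 7.13e-05), also fell.

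Of the 7 gene lists called as lower with CHX alone, 4 were also called as lower here at the preset correlation. The 75 ribosomal protein genes had a mean of −0.33 (71 negative, 4 called, 5 adjusted over the list alone, adjusted p = 6.21e-10, and adjusted p = 0.467 with an estimated correlation). The 15 glycolysis genes had a mean of −0.23 (12 negative, 1 called higher and 2 lower, 2 higher and 8 lower adjusted over the list alone, adjusted p = 0.00373, and adjusted p = 0.085 with an estimated correlation). Its called members were Gapdh1 (−0.50 ± 0.13), Tpi (−0.56 ± 0.10) and, on the other side, Pgk (0.36 ± 0.02). The 11 large heat shock genes (mean −0.67, with −0.50, −1.08 and −0.47 on the arrays, none called, 3 adjusted over the list alone, adjusted p = 0.00157) and the 44 proteasome genes (mean −0.17, none called, adjusted p = 0.00373) both had an adjusted p = 0.467 with an estimated correlation. In total 276 probes were called, 168 higher (148 named genes) and 108 lower (88 named genes), with 1554 at an unadjusted p under 0.05. Leaving out replicate 1 left 91 calls, leaving out replicate 3 left 152 and leaving out replicate 2 left 174. The series matrix gave 66, and a fit of the 3 arrays of this group alone 0. Called probes shared with CHX alone were 39 higher and 35 lower. Across probes the 2 groups correlated with r of 0.66, against 0.5 in a simulation of the 3 control extracts they share. With 0.5 µM 20E alone, 11 rises were shared, and r was 0.25 against 0.33 simulated for 2 shared extracts. The covariance went the other way, with 0.0155 against 0.00955 simulated. The simulation holds no treatment effect and lets treated and control RNA vary equally. It therefore does not decide whether these 2 groups agree beyond their shared controls.

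The difference between 20E with CHX and CHX alone asked which genes respond to 20E while translation is blocked. The grsm gene was higher by 1.27 (95% interval 0.89 to 1.65, adjusted p = 0.0399), with 1.06 ± 0.14 (SD, n = 3) in the presence of 20E and −0.21 ± 0.08 (SD, n = 3) without it. Cth was also higher by 1.27 (0.78 to 1.77, adjusted p = 0.139), Eip75B by 0.52 (0.21 to 0.84) and vri by 0.90 (0.10 to 1.70). ImpL2, a binding protein of insulin-like peptides, was higher by 1.10 (0.10 to 2.10), and none of these 4 passed the test. MsrA differed by 0.49 (−0.32 to 1.29). In all 1 probe was called, with 265 at an unadjusted p under 0.05 against 523 expected, and none of the 27 gene lists. With the replicates of both groups as pairs, grsm was again 1.27 higher but not called (adjusted p = 0.0965), and 419 probes had an unadjusted p under 0.05. This pairing is also a pairing by hybridisation day. With the label's dye orientation of 2 h replicate 2, and in a fit of the 6 arrays alone, 0 probes were called. Without any 1 of the 6 arrays grsm stayed between 1.21 and 1.34 and was not called (adjusted p = 0.0539 to 0.34). With hybridisation day as a block in the fit of 18 arrays, 4 genes were called, grsm (adjusted p = 0.0183), Cth (adjusted p = 0.0342), CG30046 and Nepl19, the last 2 chosen after their values were seen.

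Whether the response to 20E differed with and without CHX was tested as an interaction. MsrA differed by −1.81 (95% interval −2.80 to −0.82, adjusted p = 0.955), without passing the test over all probes. Its response was 2.29 without CHX and 0.49 with it. Cth differed by 0.26 (−0.35 to 0.86), Eip75B by −0.24 (−0.63 to 0.14) and vri by 0.00 (−0.98 to 0.98), intervals that leave room for differences of either sign. The 75 ribosomal protein genes differed by −0.41 on average, or by −0.07 relative to the median of the series matrix (63 negative, none called, adjusted p = 2.89e-08, and adjusted p = 0.9 with an estimated correlation). The list was not called with a dye term (adjusted p = 0.232) or with the day as a block (adjusted p = 0.303). limma called 0 probes, with 462 at an unadjusted p under 0.05, and called 25 with the day as a fixed block.

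The effect of time was the difference between 4 h and 2 h of 0.5 µM 20E. MsrA was 0.88 higher at 4 h (95% interval 0.08 to 1.69, adjusted p = 0.797), vri 0.53 (−0.27 to 1.33), Eip75B 0.05 (−0.26 to 0.37) and EcR −0.35 (−0.87 to 0.17), and none passed the test. The ribosomal protein genes were higher at 4 h by 0.29, or by 0.01 relative to the median of the series matrix (65 positive, none called, adjusted p = 6.05e-06, and adjusted p = 0.663 with an estimated correlation, 0.158 with a dye term). The large heat shock genes were lower (mean −0.56, none called, adjusted p = 0.0436, and adjusted p = 0.663 with an estimated correlation). So were the glycolysis genes (mean −0.18, none called, 1 adjusted over the list alone, adjusted p = 0.0436, and adjusted p = 0.294 with an estimated correlation). limma called 0 probes, with 641 at an unadjusted p under 0.05. Without background subtraction the large heat shock list (adjusted p = 0.0743) and the glycolysis list (adjusted p = 0.118) were not called. With a dye term, 1 of the 3 lists kept its call. limma called 1 probe with the replicate number as a block and 2 without replicate 3 of the 4 h group. With the label's dye orientation of 2 h replicate 2, 0 probes were called as well. The ribosomal (adjusted p = 0.421) and large heat shock lists (adjusted p = 0.227) then lost their calls.

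The effect of dose was the difference between 10 and 0.5 µM 20E at 4 h. MsrA differed by −0.29 (95% interval −1.10 to 0.52), Cth by 0.13 (−0.37 to 0.63), Eip75B by −0.20 (−0.52 to 0.11) and vri by 0.27 (−0.53 to 1.07). ImpE1, an ecdysone-inducible gene of imaginal discs, differed by 0.80 (−0.02 to 1.62). Of the lists, the ribosomal protein genes alone were called, with lower values at 10 µM (mean −0.34, or −0.08 relative to the median of the series matrix, 67 negative, none called, adjusted p = 1.23e-08, and adjusted p = 0.594 with an estimated correlation). With the day as a block it was not called (adjusted p = 0.86). limma called 0 probes, with 568 at an unadjusted p under 0.05, and 29 with the day as a fixed block, in which the doses share 1 day with 1 array of each.

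The 2 ecdysteroids were compared at 4 h, with 0.0625 µM PonA against 0.5 µM 20E. The doses differ, so the values stand side by side and say nothing on potency. The aos gene, which encodes a secreted inhibitor of the epidermal growth factor receptor, was lower with PonA by 0.95 (−0.95, 95% interval −1.24 to −0.65, adjusted p = 0.0407). It stood at −1.01 ± 0.16 (SD, n = 3) with PonA and −0.06 ± 0.10 (SD, n = 3) with 20E. CG10383 differed by 1.09 (0.74 to 1.44, adjusted p = 0.0407), with 0.15 ± 0.32 (SD, n = 3) after PonA and −0.94 ± 0.24 (SD, n = 3) after 20E. Another call, chosen after its values were seen, was the unnamed clone GH10215, with a difference of −1.64 (−2.16 to −1.11). The known targets did not pass, with differences of −0.57 for MsrA (−1.37 to 0.24), 0.40 for Cth (−0.09 to 0.90) and −0.30 for Eip75B (−0.62 to 0.01). They were 0.46 for vri (−0.34 to 1.26) and 0.00 for EcR (−0.52 to 0.52).

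The small heat shock genes were higher with PonA than with 20E (mean 0.47, 5 of 5 positive, none called, 1 adjusted over the list alone, adjusted p = 0.03, and adjusted p = 0.605 with an estimated correlation). Among them l(2)efl was higher by 0.27 (0.04 to 0.50, adjusted p = 0.675). In all 692 probes had an unadjusted p under 0.05. The 3 calls became 0 without background subtraction, with print-tip loess, without PonA replicate 2 or 3, and with hybridisation day as a random block. The count was also 0 with the label's dye orientation of 2 h replicate 2, without that array, and in a fit of the 6 arrays alone. There were 6 without PonA replicate 1 or 20E replicate 2, 1 without 20E replicate 3, and 6 with a dye term. Rises shared by PonA and 0.5 µM 20E numbered 10 (0.115 expected) and by PonA and 10 µM 20E 9 (0.109 expected). Across probes r was 0.48 and 0.36. All 9 arrays of these 3 groups had the treated RNA in Cy5, so that neither the correlations nor the shared rises separate treatment from dye. Called as higher with PonA and with both doses of 20E were CG5346, MsrA, Pss, Cth, grsm and Eip75B.

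In salivary glands the question was which genes 20E changes in a larval tissue that responds to the hormone before metamorphosis. No gene of the fixed lists passed the test over all probes. Eip74EF, an early ETS transcription factor, had the largest value of the early regulators, 1.29 ± 0.93 (SD, n = 3, adjusted p = 0.62). It was 0.23, 1.67 and 1.97 on the arrays, with a control signal at the level of empty spots on all 3. ImpL2 stood at 0.92 ± 0.51 (SD, n = 3, adjusted p = 0.593) and Eig71Eh, a late puff gene, at 0.80 ± 0.53 (SD, n = 3, adjusted p = 0.614). Eip75B stood at 0.46 ± 0.20 (SD, n = 3, adjusted p = 0.593). The glue gene Sgs4 stood at −0.15 ± 0.46 (SD, n = 3), MsrA at −0.02 ± 0.18 (SD, n = 3) and Cth at −0.06 ± 0.53 (SD, n = 3).

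As lists, 3 groups of genes lay higher in treated glands at the preset correlation, all with an adjusted p = 0.839 with an estimated correlation. These were the 19 early regulators (mean 0.21, 16 positive, none called, adjusted p = 0.00369) and the 23 actin and tubulin genes (mean 0.16, 16 positive, none called, 5 higher and 1 lower adjusted over the list alone, adjusted p = 0.00369, but 0.144 with a dye term). To them came the 75 ribosomal protein genes (mean 0.08, with −0.05, 0.11 and 0.18 on the arrays, 57 positive, none called, adjusted p = 0.000637). Without background subtraction the actin and tubulin and the ribosomal lists were not called (both adjusted p = 0.0515). limma called 1 probe, the unnamed clone SD05494 (1.96 ± 0.14, SD, n = 3, adjusted p = 0.0166, chosen after its values were seen). In glands 676 probes had an unadjusted p under 0.05. The call was lost without background subtraction, with print-tip loess, with a dye term and without replicate 2 or 3, and 62 probes were called without replicate 1. The 3 gland arrays share a day that holds no other array.

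The difference between glands and Kc167 cells at 0.5 µM and 4 h tested whether the responses differ by source. MsrA was lower in glands by 2.31 (−2.31, 95% interval −3.13 to −1.49, adjusted p = 0.251), with −0.02 ± 0.18 (SD, n = 3) against 2.29 ± 0.72 (SD, n = 3) in cells. Cth was lower by 1.08 (−1.08, −1.83 to −0.32, adjusted p = 0.618), and neither passed the test. Eip74EF was 1.20 higher (0.16 to 2.23, adjusted p = 0.645), and Eip75B differed by −0.31 (−0.72 to 0.10). The ribosomal protein genes were lower in glands (mean −0.22, or −0.03 relative to the median of the series matrix, 61 negative, none called, adjusted p = 1.74e-05, and adjusted p = 0.655 with an estimated correlation). The actin and tubulin genes were higher (mean 0.23, 17 positive, none called, adjusted p = 0.0265, and adjusted p = 0.655 with an estimated correlation). Without background subtraction they were not called (adjusted p = 0.0681). limma called 0 probes, with 777 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0777, and 2 probes without gland replicate 1. Day and source cannot be told apart here, since glands and cells were never hybridised on the same day.

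**Figure D3:**
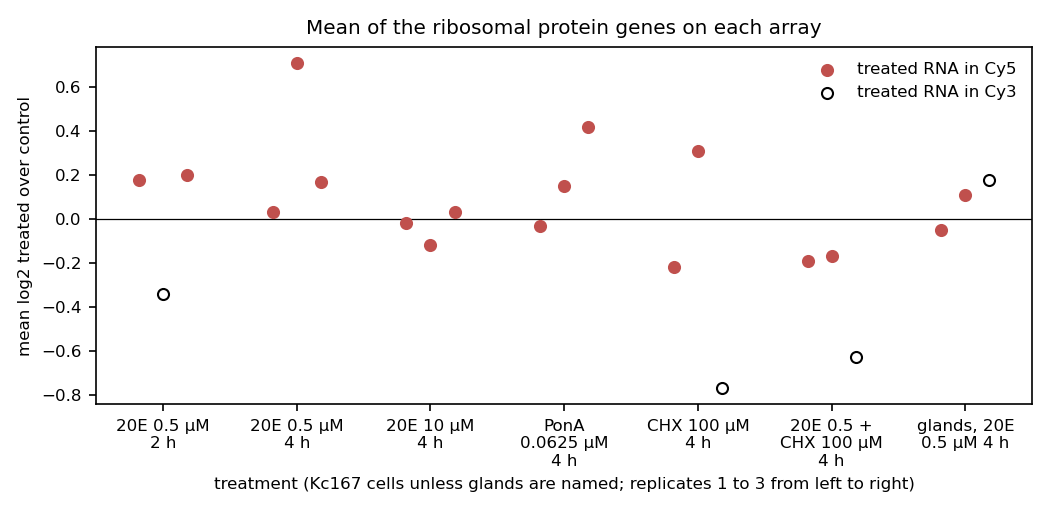
Mean log2 ratio of treated over control of 75 ribosomal protein genes on each of the 21 arrays, filled where the treated RNA was in Cy5 and open where it was in Cy3. The 3 lowest means, −0.77, −0.63 and −0.34, belong to Kc167 arrays with the treated RNA in Cy3, all hybridised on 1 day, and the list's direction with PonA turns with a dye term.

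Markers of cell types were counted where their control signal lay above the level of empty spots on most arrays. In cells and in glands these were 10 and 5 of 11 blood cell markers, 2 and 3 of 5 salivary gland markers, and 6 and 8 of 12 fat body markers. The counts were 6 and 5 of 14 muscle markers, 7 and 3 of 8 markers of neurons and glia, 3 and 3 of 10 gut markers, and 6 and 3 of 10 imaginal disc markers. In either channel, 53.3 to 63.4% of all probes lay above that level on gland arrays, against 72.1 to 93.3% on cell arrays. Of buffer spots 48.2% did so, and the counts therefore do not show which cell types were present. Besides the muscle markers with CHX, no marker list was called in any comparison. The smallest adjusted p was 0.28 for blood cell and fat body markers (glands), 0.207 for salivary gland markers (CHX), 0.0631 for neurons and glia (CHX), 0.42 for gut (20E with CHX) and 0.13 for imaginal disc (dose).

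Other fixed lists that were called in none of the 13 comparisons had these smallest adjusted p values by camera. They were 0.05 for cell death and 0.0675 for immediate early and labile regulators (both 20E with CHX, both higher), 0.118 for cell adhesion and matrix (PonA, lower) and 0.13 for cell cycle and DNA replication (dose). For nucleolar ribosome biogenesis and for chitinases and imaginal disc growth factors the value was 0.165 (both CHX), and for antimicrobial peptides 0.157 (glands minus cells). For glue secretion it was 0.207 (CHX), for late puff 71E genes 0.28 (glands), for ecdysteroid synthesis and clearance 0.289 (CHX), for autophagy 0.439 (dose) and for core histones 0.737 (dose).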

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

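The tests on the PonA calls and on the genes raised by several ecdysteroids were chosen after these results had been seen; the tests on the ribosomal protein genes and the splits of the arrays were chosen before their outcome was known.

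PonA changed 169 probes and 0.5 µM 20E 24 at the same time point, in 2 separate tests. The direct test, PonA minus 20E, called 3 probes, and without PonA replicate 3 the PonA count was 15. A difference between the compounds, in this line at these doses, stands beside 2 technical explanations. If the dye caused the PonA calls, they would share the sign of a dye coefficient estimated from 9 other arrays, whose 3 swapped arrays are also those of 1 day. Of the 169 probes, 119 (70.4%, exact 95% interval 62.9 to 77.2%) did so, against 59.6% of all probes, while all 24 probes called with 0.5 µM 20E did (100%, interval 85.8 to 100%), against 67.7% of all probes. With 10 µM 20E 17 of 21 did (81%, interval 58.1 to 94.6%), against 57.4% of all probes. The share with 0.5 µM 20E is not like for like, since some of the 9 arrays share control extracts and days with 2 of the 3 arrays of 0.5 µM 20E. The PonA share is not independent either, since its control extracts are, per the labels, also those of the 2 h arrays among the 9. The intervals take probes as independent, which they are not, and may be too narrow. A part of the PonA calls could be due to the dye, since all 3 arrays had one orientation. Day and treatment cannot be told apart, because all 3 PonA arrays and no other were assigned to 1 day, and a missing date is not excluded for them. With the day as a random block 32 probes were left.

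A set of 14 probes (11 named genes) rose with more than 1 of 0.5 µM 20E, 10 µM 20E and PonA at 4 h, and 8 of them with all 3. In 10000 random draws of lists of these sizes at most 4 probes recurred. The draws take the 3 lists as independent. The groups, however, share the dye orientation and a joint estimate of each probe's spread, which could also make probes recur. The draws therefore argue only against independent lists. The dye as the whole cause was argued against by another comparison. In the 3 pairs of arrays of 20E with CHX and CHX alone, which share dye orientation and day, the medians of the 14 probes were 1.02, 1.41 and 1.08 on the log2 scale, with 13 of 13, 12 of 14 and 14 of 14 measured values positive, while the middle 95% of medians of random sets lay within −0.16 to 0.16. These genes may be a shared ecdysteroid response in Kc167 cells that continues while translation is inhibited. This hypothesis was formed after the results were seen. It was tested on other arrays of the same series, some of which share control extracts and days with those of 0.5 µM 20E. MsrA and Pli do not follow it, with pair values of 0.65, −0.07 and 0.88 for MsrA and 0.30, −0.13 and 0.14 for Pli.

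The 75 ribosomal protein genes shifted together in 9 of the 13 comparisons at the preset correlation, up in some and down in others, and none of these 9 calls held with an estimated correlation. With a dye term the list turned from up to down for PonA. Signal intensity was tested with gene sets of like intensity. In 9 of the 9 comparisons the list median lay outside the middle 95% of these sets, whose own medians ran from −0.08 to 0.08. Some margins were small, as in glands (0.06 against an upper limit of 0.04). Each array was normalised on intensity, the comparisons were those that called the list, and the sets take genes as independent. That outcome was therefore likely beforehand. It shows that genes of like intensity shifted less, and no further conclusion on intensity is drawn. A dye effect would turn the sign on the swapped array of a group, which it did in 2 of the 4 groups that have one. The means were −0.34 on the swapped array against 0.19 on the others at 2 h, −0.77 against 0.04 with CHX, −0.63 against −0.18 with 20E and CHX, and 0.18 against 0.03 in glands. A dye effect could therefore account for a part of these shifts, and a biological one stays open, as the 3 swapped Kc167 arrays also share a hybridisation day.

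Other splits or sign patterns of the same arrays were counted for each comparison, and in 12 of the 13 they are too few for a share under 0.05. For the 7 comparisons with control, the real sign pattern was 1 of 4, and no other called as many probes. The highest other counts were 0 at 2 h, with 0.5 µM 20E, with 10 µM 20E, with PonA and in glands, 1 with CHX and 3 with 20E and CHX, against real counts of 5, 24, 21, 169, 1, 116 and 276 in that order. For time, dose and glands minus cells, all 10 of 10 splits called at least the real count of 0, as any split must, with a highest other of 1, 0 and 0. For PonA minus 20E, 1 of 10 splits reached the real 3, and the highest other was 1. For 20E with CHX minus CHX, 4 of 10 reached the real 1, and the highest other was 3, in a split that keeps the arrays of replicate 2 together; the other splits that part all 3 pairs called 0. For the interaction, 100 of 100 splits reached the real 0, again as any split must, so that the count says nothing on chance. The highest other, 658, points to a structure of the arrays, whose cause was not tested.

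Some genes had values of opposite sign on every array of glands and of Kc167 cells after 0.5 µM 20E at 4 h, and the difference was not tested beyond the limma comparison given above, which called 0 probes. Of 107 genes looked at, 7 had such values, and none of them was called in glands. Random signs would give 3.34, a number too low for genes chosen for having all cell arrays on one side, such as CG17760 and PRL-1. No conclusion on chance is drawn from it. On the cell arrays Eip78C stood at 0, −0.04 and 0 after rounding. The difference, glands minus cells, was 0.37 for Eip78C (0.35 against −0.02), 0.15 for crol (0.07 against −0.08), 0.2 for Cyp18a1 (0.12 against −0.08), 0.71 for Act79B (0.47 against −0.25), −1.43 for CG17760 (−0.18 against 1.25), −1.27 for PRL-1 (−0.19 against 1.08) and 0.31 for Mtp (0.18 against −0.13). Between 4 h and 2 h of 0.5 µM 20E, 2 of 84 genes had opposite signs on every array, against 2.62 from random signs, and this was likewise not tested. Here too some genes, CG12708 among them, had been chosen for having all 4 h arrays on one side. The difference was −0.57 for CG12708 (−0.45 against 0.12) and 0.53 for AttA (0.39 against −0.15).

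Signal was also seen at spots that no comparison uses. Of the spots recorded as failed amplifications, 20.1% lay above the level of empty spots, with 11.9 to 33.5% per array. The share was 9.15% of the empty spots themselves, from which the level was set, and 70.3% of gene spots. It was 48.2% of buffer spots, 39.6% of other control sequences and 99.6% of sample pool spots. Lying above this level therefore does not by itself show that a transcript was detected. The cause of the signal at failed and buffer spots was not tested.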

How the results depend on the processing

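The label's dye orientation, the fit without 2 h replicate 2, the day as a block, the filter at the level of empty spots and the median-centred matrix were chosen after the results were seen, and the other alternatives before. Of 11456 values of named genes under alternatives, 10164 counted as unchanged, 715 were no longer called and 52 became called with the same sign. Unchanged means, for a value called in the main fit, that call and direction were kept. For the others it means no call and a move under 1 SD, whatever the sign. Another 523, not called in the main fit, moved by 1 SD or more or became called with the other sign. Of the values called in the main fit, 2 changed sign. With PonA, Eip75B was −0.07 (adjusted p = 0.705) in the series matrix, above its median of −0.5 and so not lower relative to it, and Rpn8 0.17 (adjusted p = 0.632) in the median-centred matrix. The counts below are probes called, and unless a reason is given the cause was not tested.

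With the dye term, 3 probes were called at 2 h, 4 with 0.5 µM 20E at 4 h, 8 with 10 µM 20E, 61 with PonA, 0 in glands and 6 for PonA minus 20E. With the label's dye orientation, 0 were called at 2 h, 4 with 0.5 µM 20E, 0 with 10 µM 20E, 0 for PonA minus 20E and 0 for 20E with CHX minus CHX. Apart from 2 h, this orientation left the values of these comparisons unchanged and acted through the shared spread. Without the array of conflicting dye, 0 were called at 2 h and 0 for PonA minus 20E. In fits of only the arrays compared, which have fewer arrays, counts were 0 at 2 h, 0 with 0.5 µM 20E, 0 with 10 µM 20E, 2 with PonA, 0 with CHX, 0 with 20E and CHX, 0 for PonA minus 20E and 0 for 20E with CHX minus CHX.

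Without background subtraction, 83 probes were called with 10 µM 20E, 0 in glands, 0 for PonA minus 20E and 4 for 20E with CHX minus CHX. With print-tip loess the counts were 0 in glands, 0 for PonA minus 20E and 2 for 20E with CHX minus CHX. With the series matrix values they were 3 at 2 h, 11 with 0.5 µM 20E, 79 with 10 µM 20E, 5047 with PonA, 24 with CHX, 66 with 20E and CHX, 0 in glands and 3174 for PonA minus 20E. The median of the matrix lay at −0.5 for PonA, and 4889 of the 5047 were lower. With its column medians subtracted, the counts were 4 with 0.5 µM 20E, 107 with 10 µM 20E, 2117 with PonA, 58 with CHX, 74 with 20E and CHX, 12 in glands and 0 for PonA minus 20E. With a minimum of 1.5-fold, 181 were called with 20E and CHX, and with the filter at the level of empty spots 3 in glands and 1 for glands minus cells.

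With the day as a random block, 12 probes were called with 10 µM 20E, 32 with PonA and 0 for PonA minus 20E. With the day as a fixed block, 29 were called for dose, 4 for 20E with CHX minus CHX and 25 for the interaction. With the control extract as a random block, 6 were called for 20E with CHX minus CHX. With the replicate block, 1 was called for time, 9 for PonA minus 20E, 0 for 20E with CHX minus CHX, where the replicates are paired, and 1 for the interaction; the block changed no other call.

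Leaving out 1 array at a time, gave 0 to 0 probes at 2 h, 6 (without replicate 2) to 33 with 0.5 µM 20E, 0 to 45 with 10 µM 20E, 15 to 193 with PonA, 30 to 158 with CHX, 91 to 174 with 20E and CHX, 0 to 62 in glands, 0 to 2 for time, 0 to 0 for dose, 0 to 6 for PonA minus 20E, 0 to 1 for 20E with CHX minus CHX, 0 to 0 for the interaction and 0 to 2 for glands minus cells. Of the 31 gene list calls, 1 held with an estimated correlation, which allows for genes that move together. Calls kept by the same lists were 22 of 31 without background subtraction, 22 of 31 with the dye term, 22 of 26 with the day as a block and 21 of 26 with the label's dye orientation. The filter on probes not above local background changed no count.

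Signal over background limits the gland arrays, where 53.3, 63.4 and 53.3% of probes lay above the level of empty spots. Whether changes of low transcripts were missed there was not tested.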

Other observations

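The comparison of the recurrent genes with the other groups was chosen after the results were seen. The 14 probes that rose with more than 1 of 0.5 µM 20E, 10 µM 20E and PonA at 4 h also had positive values at 2 h, and include the 5 probes called there. All 14 were positive at 2 h, with a median of 0.87 (from 0.34 to 1.98) on the log2 scale, where the middle 95% of medians of random sets of 14 probes spanned −0.08 to 0.08. With the label's dye orientation of 2 h replicate 2 the median was 0.57, with 13 positive. In salivary glands 8 of the 14 were positive and the median was 0.02, inside the random range of −0.06 to 0.06, with grsm at 1.00, Rrp46 at 0.76, Eip75B at 0.46 and PRL-1 at −0.19. With CHX alone the median was −0.07 (5 positive; random range −0.08 to 0.07), and with 20E and CHX together 0.97 (12 positive; random range −0.10 to 0.09). The 2 h and PonA labels describe identical extracts, and some control extracts served several groups, so the groups are not independent.

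A dye term was also fitted over the 18 Kc167 arrays, of which 3 were swapped. These 3 are all the arrays of 1 hybridisation day, so that dye and day cannot be told apart in it. The term was called by limma for 285 of 10474 probes, and 2391 had an unadjusted p under 0.05. Its median absolute value was 0.082 on the log2 scale, against 0.099 for the group with 0.5 µM 20E at 4 h. The other groups are not part of the value of 0.099. Across probes, pairs of these Kc167 arrays from different groups had a median r of 0.20 with the same dye orientation (96 pairs) and −0.06 with opposite orientation (39 pairs). Within groups these medians were 0.24 (12 pairs) and 0.11 (6 pairs). Among these arrays, pairs from the same day all have the same orientation, and so have the pairs with a shared control extract except 1, so that these medians do not separate the dye from day and extract.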
